A study of Homo sapiens with 7 samples.

How the data were processed

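The cells were Hep3B, an established human hepatoma line, as wild-type cells and as lines in which Smad2, Smad3 or Smad4 was knocked down. Smad2 and Smad3 are the receptor-activated Smads of the TGF-β pathway, and Smad4 is their common partner. Per the labels, stimulation lasted 12 h at 5 ng/ml TGF-β, the extracted RNA was amplified linearly by the Eberwine method, and labelled DNA was made with Klenow enzyme and hybridised to arrays of sense oligonucleotides with Cy3 and Cy5. Each of the 7 samples was a comparison of a pair of RNAs, and each comparison had 1 sample: stimulated over unstimulated wild-type cells, each knockdown line over wild-type cells with both stimulated, and each knockdown line over wild-type cells with both unstimulated. The labels name both dye orders for each channel of each sample. Whether a dye-swapped pair of hybridisations lies behind each value, and the scanner, the image software, the background correction and the normalization, are not given in the sources used here.

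The deposited values were read as log2 ratios. The log2 scale was settled from the values: 2 raised to the value was a number of at most 4 decimals, within 0.02 of the last decimal, for 100% of the 75570 deposited values, against 4.28% with base e and 3.83% with base 10. The medians of the 7 samples lay between −0.03 and 0.01, and whether and how the ratios were centred stays unknown. The direction was taken as likely the first named channel over the second. The basis was the order of the channels in the labels together with the targeted Smad, which was lower in its own line in all 6 knockdown samples. Between 9959 and 11425 of the 21329 probes had a value in a sample, 8167 had one in all 7 and 8011 had none in any. The rule by which probes lost their value is not given in the sources used here, and no signal intensities were used here.

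Probes were named through the platform annotation, which is old, with symbols looked up by gene ID in the RefSeq gene table. Of the probes, 16870 had 1 gene symbol, 172 had several and 4287 were unnamed here. The gene IDs of 16779 probes were found in the RefSeq table, which changed 0 symbols, and 91 probes with 1 gene kept the annotation's symbol. Probes with several symbols were left out of all gene counts, and unnamed probes were counted apart. A gene's value was the mean of its probes, which gave 10436 genes with a value in at least 1 sample and 6914 with a value in all 7. No coordinates are given, because the array design carried none that were used here.

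With 1 sample per comparison there was no replicate check and no test across samples, and no p-values were computed across genes. A gene was called higher or lower at a ratio of at least 2-fold, which is a threshold of size and not a test; the words rose, fell and changed refer to it. The measure of error of single ratios was the SD between both probes of genes measured by 2 probes within a sample. Bootstrap SEs were SDs over 1000 draws with replacement, of genes for medians and a covariance and of probe pairs for ratios of counts, and so leave out variation between samples. A gene that responded in wild-type cells was called opposed by a knockdown if the knockdown changed it by at least 2-fold the other way with TGF-β, and it was set aside as off-target if the same line without TGF-β had changed it by at least 2-fold in that same direction. The response to TGF-β within a knockdown line was computed per gene as the wild-type response plus the knockdown ratio with TGF-β minus the knockdown ratio without it, so that the errors of 3 samples add up in it.

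A list of genes was described by its median log2 ratio, the number of members past 2-fold and the percentile of its median among 10000 random lists of the same size drawn with replacement from the genes with a value. The random lists were not matched on expression, because the values hold ratios only. A percentile places the list's median among random lists and does not measure the spread over its members. The 18 lists were TGF-β/Smad immediate targets, TGF-β receptors with ligands and Smads, extracellular matrix and cytoskeleton, epithelial junctions, hepatocyte secreted proteins (which also held hepatocyte enzymes and transcription factors), cell cycle and DNA replication, apoptosis, interferon-stimulated genes, inflammatory and acute phase genes, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein and amino acid response, cytosolic ribosomal proteins, metallothioneins, core histones, and markers of fibroblasts and stellate cells, of blood and immune cells and of endothelium. Comparisons that share a wild-type RNA share its chance deviations. Overlaps were therefore set beside the overlap of independent lists and beside 100 simulations in which no gene had an effect, all of the observed spread was noise, and the wild-type RNA was the same on all arrays that used it. All RNAs had equal noise in these simulations, which overstate the noise but set no bound, since a wild-type RNA noisier than the others would give more.

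The thresholds, lists, designs, alternatives and the rule for named genes were fixed before the data were examined. The rule took genes with 1 symbol, a value in all 7 samples and all probes of the same sign: the 10 highest and 10 lowest of the wild-type response, the 5 highest and 5 lowest of each knockdown sample, list members past 2-fold with at most the 4 largest of a list in a sample, after off-target genes were set aside at most 10 genes opposed by all 3 knockdowns and the 4 with the largest wild-type responses opposed by each knockdown alone, and at most 5 higher and 5 lower genes changed the same way in all 3 lines without TGF-β. SMAD2, SMAD3 and SMAD4 were always named. SMAD7, which the rule also names, is not analysed here, and a further item of the rule is not reported here. Genes outside the rule are said to be so. The alternatives were thresholds of 1.5-fold and 3-fold, a threshold of 3 robust SDs of each sample (from the scaled median absolute deviation), median centring, the strongest probe per gene, every probe on its own, genes with a value in all samples, samples scaled to an equal robust SD, and means in place of medians. Thresholds scaled to the median and to the root mean square of each sample's probe-pair SD were added after the data had been seen. The counting was tested on simulated data for the wild-type response and the Smad3 knockdown over 10436 genes, with normal noise at the median probe-pair SD. Of 200 changed genes 97.5% were recovered at a change of 1.5 on the log2 scale and 100% at a change of 3, with 0 false calls. That noise was small against the 2-fold threshold, so the 0 followed from the setting. The root mean square SDs of these samples were larger (0.413 and 0.318). The check covers the counting only and gives no rate of false calls in the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.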

Results

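Transcript ratios were measured in 7 comparisons of Hep3B hepatoma cells on oligonucleotide arrays, with the aim, as the series states it, of finding genes that TGF-β controls through each Smad and of recognising false positives of the knockdowns. Stimulated wild-type cells were compared with unstimulated ones, and lines with a knockdown of Smad2, Smad3 or Smad4 were compared with wild-type cells, once with TGF-β and once without. Each comparison had 1 sample, so none of the values below has a replicate check, and a change means a ratio of at least 2-fold. Named genes with a value numbered 8456 for the wild-type response, 8092, 9066 and 8726 for the Smad2, Smad3 and Smad4 knockdowns with TGF-β, and 8860, 8836 and 9218 without it. All directions are likely ones, read from the order of the channels. Rankings of genes are among those with a value in all 7 samples, unless said otherwise.

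SMAD2 mRNA in the Smad2 line was at 22.6% of the wild-type level with TGF-β (log2 ratio −2.15) and at 60.8% without it (−0.72). SMAD3 mRNA in the Smad3 line was at 52.2% (−0.94, with its probes at −1.15 and −0.72) and at 51.4% (−0.96). SMAD4 mRNA in the Smad4 line was at 56.4% (−0.83) and 46.6% (−1.10). The targeted mRNA thus passed 2-fold in 2 of the 6 samples, SMAD2 with TGF-β and SMAD4 without. The Smads that were not targeted lay between 75.9% and 146% of wild type, the extremes being SMAD3 in the Smad4 line and SMAD4 in the Smad3 line, both with TGF-β. In wild-type cells TGF-β raised SMAD3 to 2.63-fold (1.39), while SMAD2 was at −0.12 and SMAD4 at −0.34.

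**Figure D1:**
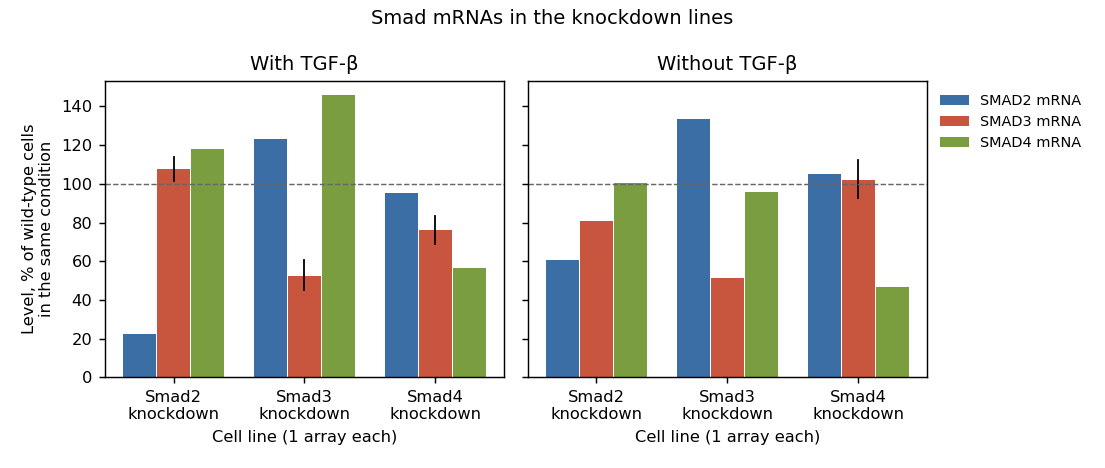
Levels of the SMAD2, SMAD3 and SMAD4 mRNAs in each knockdown line as a percentage of wild-type cells in the same condition, with TGF-β (left) and without (right). Each bar is the mean of the gene's probes in 1 sample, black lines join the lowest and highest probe where 2 probes had a value, and the dashed line marks 100%. The lowest bar is SMAD2 in the stimulated Smad2 line, at 22.6%.

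The first comparison asked which genes TGF-β changes in wild-type cells. Among genes with a value in all 7 samples CER1, which encodes the Nodal and BMP antagonist Cerberus, rose 179-fold (7.49), followed by CRYAA (4.59), SEMA3G (4.55), IGFBP7 (4.33), RASL11B (4.30), PLXDC2 (4.14), the glycolytic regulator PFKFB3 (3.90), ASAP2 (3.87), the gap junction gene GJA1 (3.80) and the lysyl oxidase family member LOXL4 (3.79). Among the decreases the kininogen gene KNG1 fell by 3.98 on the log2 scale, followed by PCOLCE2 (−3.81), ASPH (−3.35), the ecto-5′-nucleotidase gene NT5E (−3.14), the type II collagen gene COL2A1 (−3.07), the liver fatty acid binding protein FABP1 (−2.91), IGFBP3 (−2.85), NADK2 (−2.83), AMDHD1 (−2.75) and the ERK phosphatase DUSP6 (−2.66). In total 375 genes rose and 319 fell, 8.21% of those measured, along with 119 unnamed probes. The probes of a changed gene had the same sign in 20 of the 22 changed genes that had several, and the median SD between both probes of a gene was 0.22.

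Immediate targets of the pathway rose as a group. Of 20 measured members 14 rose and 0 fell, with a median of 1.45 at percentile 100 of the random lists. Among them were the stress gene GADD45B (3.41), the cell cycle inhibitor CDKN1A (2.62), JUNB (2.14) and BHLHE40 (2.13). Of the receptors, ligands and Smads, 5 of 17 rose and 0 fell, namely the activin antagonist FST (3.00), the receptors ACVR1 (2.35), BMPR2 (1.49) and TGFBR1 (1.29), and SMAD3; the list's median of 0.07 lay at percentile 71.0. In the matrix and cytoskeleton list 9 of 23 rose and 0 fell, with a median of 0.88 at percentile 100, including the collagen cross-linking enzyme LOX (2.62), the protease inhibitors TIMP3 (2.21) and TIMP1 (2.10), and TNC (2.05). Among epithelial junction genes 2 of 14 rose and 1 fell, with a median of 0.34 at percentile 99.6 but a bootstrap SE of 0.26 and a mean of 0.12, and KRT18 reached 1.05.

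In the hepatocyte list, mostly secreted proteins but with the transcription factors FOXA2 (−1.06) and CEBPA (0.03) among its measured members, 10 of 20 fell, FOXA2 included, and 0 rose, with a median of −1.003 at percentile 0. Among those that fell were the transport protein TTR (−2.10), the fibrinogen chain FGB (−1.99), APOH (−1.91) and ITIH2 (−1.51). Cholesterol synthesis genes had a median of −0.58 at percentile 0, although only INSIG1 (−1.40) and MSMO1 (−1.10) of 13 fell. Inflammatory and acute phase genes had a median of −0.24 at percentile 1.80 with 3 of 14 lower, among them the complement gene CFB (−2.43). The unfolded protein list had a median of −0.25 at percentile 2.31 with 0 of 12 lower and only the glutathione-degrading CHAC1 (1.25) higher. Interferon-stimulated genes lay at a median of 0.37, percentile 99.6, with 0 of 12 past the threshold.

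Of the remaining lists, all but the immune markers and metallothioneins had medians between percentiles 38.9 and 92.7 of the random lists in wild-type cells. Cell cycle genes had a median of 0.10 with 0 of 31 changed, ribosomal proteins −0.01 with 0 of 19, and core histones 0.01 with 0 of 7. Among apoptosis genes (0.06) the effector BAX (−1.50) and GADD45A (−1.16) fell while BCL2L11 (1.04) rose. Among glycolysis and hypoxia genes (0.16) PFKFB3 and DDIT4 (1.55) rose and NDRG1 (−1.71) fell. Fibroblast and stellate markers had a median of −0.02 with 2 of 10 higher, and endothelial markers 0.00 with 1 of 8 lower. Only 4 blood and immune markers were measured, with a median of −1.08 at percentile 0.16 and 2 lower. Metallothioneins had values for 2 genes here, neither changed, and reached 3 genes in the unstimulated Smad4 line alone, where the median was −0.20.

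The knockdown lines were compared with wild-type cells under TGF-β to find genes whose stimulated level depends on a Smad. In the Smad2 line 62 genes rose and 102 fell. Among genes with a value in all samples, the steepest decreases were in the trypsin inhibitor SPINK1 (−5.64), the defensin DEFB1 (−5.45), the RNA-binding protein RBM47 (−4.57), FGB (−4.36) and the glutathione peroxidase GPX2 (−4.08). The largest increases among these genes were in GJA1 (1.99), TBC1D16 (1.96), FSTL1 (1.92), OSGIN1 (1.81) and CCDC102A (1.74). The hepatocyte list had a median of −0.42 (bootstrap SE 0.32) at percentile 0, with 0 of 20 members higher and 6 lower, including the iron carrier TF (−1.93), AFP (−1.49) and HPX (−1.32). Ribosomal proteins had a median of −0.30 at percentile 0 with 1 of 20 past the threshold. Matrix genes had a median of 0.31 at percentile 100; 2 of 22 were higher, COL5A2 (1.62) and TIMP3 (1.42), and 1 was lower, the integrin ITGA5 (−1.50), which lacks a value in some samples and was named after its value was seen. Other list medians lay high or low among the random lists in the same sample. Endothelial markers were at 0.30 (percentile 99.0, 0 of 6 members past 2-fold) and cholesterol synthesis genes at 0.23 (99.4, 0 of 13). Apoptosis genes were at 0.17 (97.8, 1 of 15 higher) and core histones at −0.31 (1.16, 1 of 7 lower). Less extreme were fibroblast and stellate markers (0.21, 96.8, 0 of 8), cell cycle genes (0.11, 96.6, 0 of 31) and glycolysis and hypoxia genes (−0.17, 2.945, 0 of 17). In the junction list the adhesion gene CDH1 was lower (−1.12), 1 of 14. The immediate targets had a median of 0.23 at percentile 99.9, and CDKN1A (−2.54) alone of 19 fell. Their mean was 0.024.

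In the stimulated Smad3 line 212 genes rose and 136 fell. Among genes with a value in all samples, the 5 highest ratios belonged to genes that TGF-β had lowered in wild-type cells: ASPH (2.83), DUSP6 (2.36), NT5E (2.23), the protease inhibitor A2M (2.20) and PEG10 (2.06). The 5 lowest belonged to genes it had raised: CER1 (−3.22), RASL11B (−2.26), the serine protease HTRA1 (−2.22), GSTT2 (−2.17) and SHB (−1.95). Of the immediate targets CDKN1A (−1.84), GADD45B (−1.73) and the decoy receptor BAMBI (−1.15) fell, 3 of 23, at a list median of −0.15 and percentile 5.49. Cholesterol synthesis genes had a median of 0.35 at percentile 99.7, with MSMO1 (1.36), INSIG1 (1.23) and STARD4 (1.17) higher. Interferon-stimulated genes had a median of −0.225 at percentile 1.62, with 0 of 14 past the threshold. Of 25 matrix genes 2 fell, TNC (−1.81) among them, and 1 rose, ITGAV (1.14). LDHA (−1.51) was the 1 of 19 glycolysis genes that changed. Of 14 inflammatory genes 2 rose, ICAM1 (1.62) among them, and 1 fell, TNFAIP3 (−1.31).

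In the stimulated Smad4 line 38 genes rose and 101 fell. The immediate targets had a median of −0.42 at percentile 0, with 3 of 19 lower, among them CDKN1A (−2.11) and TGFBI (−1.03). Among genes with a value in all samples, the lowest ratios were those of HTRA1 (−2.70), GPX2 (−2.25), DEFB1 (−2.24), CDKN1A and RASL11B (−1.99). The highest among these genes were those of the lymphotoxin gene LTB (2.19), BAX (1.75), JAML (1.65), CAVIN2 (1.62) and the cadherin CDH10 (1.57). The hepatocyte list had a median of 0.19 at percentile 99.4, with 1 of 20 lower, FGB (−1.35), and TIMP1 rose (1.06), the 1 of 23 matrix genes that changed. Inflammatory genes had a median of 0.24 at percentile 99.4, with 0 of 13 past the threshold. At 3 robust SDs of each sample in place of 2-fold, the changed genes numbered 276 in the Smad2 line, 394 in the Smad3 line and 232 in the Smad4 line.

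The unstimulated comparisons were made to find genes that differ between the lines without TGF-β. Fewer genes passed 2-fold: 17 up and 33 down in the Smad2 line, 34 and 17 in the Smad3 line, and 5 and 8 in the Smad4 line. The excess of decreases in the Smad2 line depended on the threshold: 34% of its changed genes were higher at 2-fold, 48.4% at 1.5-fold and 51.5% at 3 robust SDs. COL2A1 was the highest in both the Smad2 line (3.95) and the Smad3 line (3.92) but was at −0.31 in the Smad4 line, and A2M followed it in both (1.69 and 1.9995) among genes with a value in all samples, to which the names that follow are limited too. The Smad2 line also had higher C4BPA (1.67), OSGIN1 (1.30) and CFB (1.22), and lower SPINK1 (−2.90), the cytokine IL32 (−2.70), FGB (−2.40), MPP1 (−2.14) and CDKN1A (−2.12). In the Smad3 line the α-fetoprotein gene AFP (1.83), GPX2 (1.62) and TSPAN8 (1.62) were higher, and SPANXN3 (−1.59), the hormone subunit CGA (−1.22), the chemokine CXCL6 (−1.20), NTS (−1.20) and CD74 (−1.16) were lower. In the Smad4 line TSPAN8 (1.55), TIMP1 (1.27), AFP (1.23) and DKK3 (1.20) were higher and NTS (−1.24), CDKN1A (−1.23), HTRA1 (−1.17) and SMAD4 were lower; the next of these genes, CDKN1C (0.93) and DEFB1 (−0.96), did not reach 2-fold. DKK3, a member of the Dickkopf family of Wnt regulators, was the only gene past 2-fold in the same direction in all 3 lines (1.09, 1.54 and 1.20).

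Among the lists, the unstimulated Smad2 line had interferon-stimulated genes at a median of −0.19 (percentile 0.03, bootstrap SE 0.11) and ribosomal proteins at −0.12 (percentile 1.38, SE 0.02), with 0 members past the threshold in either. Inflammatory genes had a median of −0.31 at percentile 0 in the Smad3 line, with 1 of 14 lower, core histones −0.21 (percentile 1.70) and the 4 immune markers 0.26 (97.8). Cholesterol synthesis genes had a median of −0.20 at percentile 0.01 in the Smad4 line, with 0 of 13 past the threshold, the hepatocyte list 0.13 (99.8) and fibroblast and stellate markers −0.13 (2.04). The median probe-pair SD was 0.10, 0.11 and 0.10 in the unstimulated Smad2, Smad3 and Smad4 samples, against 0.16, 0.18 and 0.16 in the stimulated ones. At 3 robust SDs of each sample the counts without TGF-β were 264, 219 and 216, against 276, 394 and 232 with it.

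Next, the wild-type response was set against each knockdown gene by gene. The Smad3 knockdown opposed 173 of 630 responsive genes at 2-fold (27.5%), the Smad4 knockdown 73 of 624 (11.7%) and the Smad2 knockdown 30 of 594 (5.05%). Independent lists would share 11.1, 4.53 and 5.50 genes, and the simulations of a shared wild-type RNA without any effect gave means of 84.0 (69 to 100), 43.9 (34 to 56) and 50.5 (39 to 64). Counting sign alone, 87.1% of responsive genes were opposed in the Smad3 line, 82.1% in the Smad4 line and 47.6% in the Smad2 line. The knockdown went further in the direction of the response at 2-fold for 35 genes in the Smad2 line, 2 in the Smad3 line and 5 in the Smad4 line. The stimulated wild-type RNA enters the pair of ratios with opposite signs, so these counts are not free of its chance deviations.

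**Figure D2:**
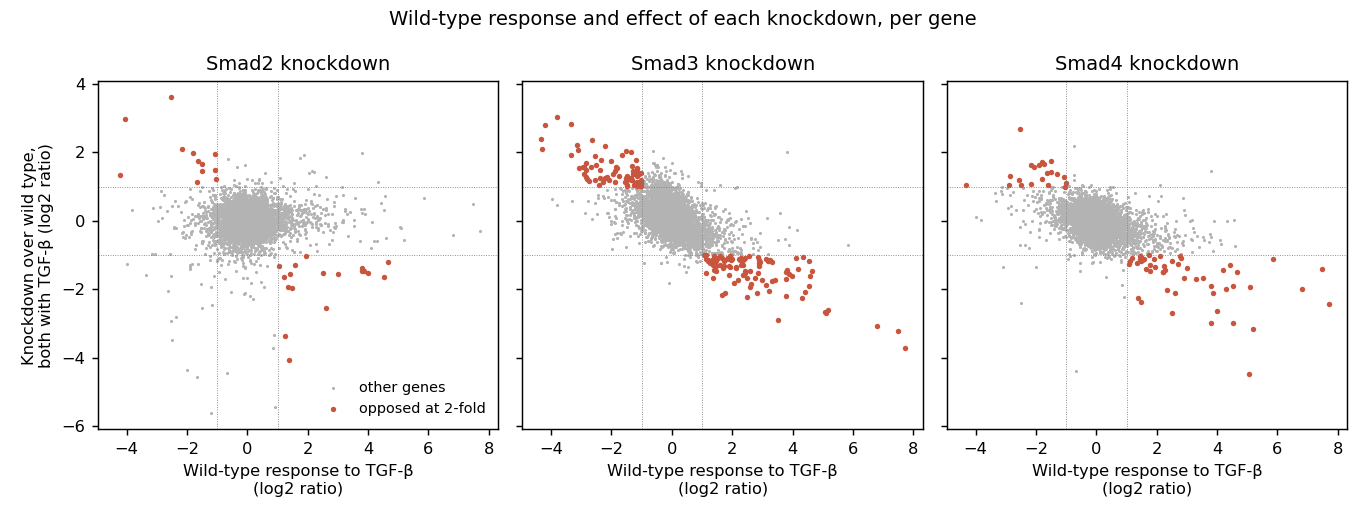
Each point is a gene, with its wild-type response to TGF-β on the horizontal axis and its ratio of knockdown over wild-type cells, both with TGF-β, on the vertical axis (log2 ratios, 1 sample each; dotted lines at 2-fold). Red points are genes opposed at 2-fold, 30 for Smad2, 173 for Smad3 and 73 for Smad4.

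After off-target genes (5, 6 and 2 for Smad2, Smad3 and Smad4) and genes without a value in the unstimulated line (11, 32 and 29) were set aside, 14 opposed genes were left for Smad2, 135 for Smad3 and 42 for Smad4. The term off-target is that of the labels. A change without added TGF-β may also come from the loss of the targeted Smad, which was not tested. CDKN1A, a member of the immediate targets, was set aside for Smad2 (−2.54 with TGF-β and −2.12 without) and for Smad4 (−2.11 and −1.23). HTRA1 was set aside for Smad4 (−2.70 and −1.17). Only FST and SCN9A were left for all 3 knockdowns among genes with a value in every sample. Of the 11 opposed by all 3 before screening, CDKN1A and HTRA1 were set aside as off-target. The rest, outside the rule for named genes, lacked some or all unstimulated values: SPINK2 (4.65 in wild-type cells), MRC2 (3.99), CFHR2 (3.88), COXFA4L3 (3.81), CILP (3.79), TUBA4B (1.93) and EML1 (1.47). Screening left 5 of 18, 68 of 100 and 24 of 52 opposed genes raised by TGF-β for Smad2, Smad3 and Smad4. Of those lowered, 9 of 12, 67 of 73 and 18 of 21 were left. FST rose by 3.00 with TGF-β and was at −1.55, −1.74 and −1.38 in the stimulated Smad2, Smad3 and Smad4 lines, and the sodium channel gene SCN9A fell by 1.02 on the log2 scale and was at 1.23 and 1.15 in the Smad2 and Smad3 lines and exactly at 2-fold in the Smad4 line. Of the genes opposed by 1 knockdown alone that were left and had a value in every sample, the 4 with the largest wild-type responses are named for each line. For Smad3 they were CRYAA (−1.62), SEMA3G (−1.17), IGFBP7 (−1.05) and GADD45B (−1.73). In the unstimulated Smad3 line these 4 were at −0.93, −0.46, −0.53 and −0.25. In the stimulated Smad4 line they were at −0.73, 0.03, −0.002 and −0.78, and in the Smad2 line at −0.49, 0.74, 1.14 and 0.27. Their computed responses inside the Smad3 line were 3.90, 3.83, 3.80 and 1.94, against 4.59, 4.55, 4.33 and 3.41 in wild-type cells. For Smad4 they were ENC1 (−1.66 against a response of 2.92), the keratin KRT80 (−1.27 against 2.69), the pseudokinase TRIB1 (−1.18 against 2.51) and the collagen prolyl hydroxylase P3H2 (−1.32 against 2.23). In the unstimulated Smad4 line these 4 were at 0.05, −0.01, 0.33 and −0.007. In the stimulated Smad3 line they were at −0.36, −0.97, 0.09 and −0.96, and in the Smad2 line at −0.22, −0.67, −0.33 and 0.43. For Smad2 they were the transcription factor MAF (1.13 against −1.65), SERPINA3 (−1.29 against 1.58), SNX10 (−1.63 against 1.21) and ZW10 (−1.31 against 1.06). In the unstimulated Smad2 line these 4 were at 0.88, −0.57, −0.74 and −0.27, and their computed responses inside that line were −1.41, 0.86, 0.32 and 0.03. In the stimulated Smad3 line they were at 0.78, 1.04, 0.01 and −0.17, and in the Smad4 line at −0.56, 0.23, −0.77 and −0.90. The word alone thus refers to the 2-fold threshold, which several of these genes missed narrowly in another line. Before that screening, and over the 565 responsive genes with a value in all 3 stimulated lines, 371 were opposed by none, 120 by Smad3 alone, 28 by Smad4 alone, 7 by Smad2 alone, 23 by Smad3 and Smad4, 5 by Smad2 and Smad4, 0 by Smad2 and Smad3, and 11 by all.

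The response to TGF-β inside each knockdown line was then computed. It had a median size of 70.3% of the wild-type response in the Smad3 line over 561 responsive genes, 79.7% in the Smad4 line over 541 and 110% in the Smad2 line over 518. The genes were picked by the wild-type ratio, which is also the divisor. If wild-type RNAs were shared, this choice could lower the percentages without any effect of a Smad. In the Smad2 line SMAD2 mRNA was at 22.6% of wild type with TGF-β and 60.8% without it. Its computed response therefore also holds this difference in depletion. CER1 still responded by 5.33 in the Smad3 line, 6.48 in the Smad4 line and 8.27 in the Smad2 line, against 7.49 in wild-type cells. The immediate targets had median responses of 1.03, 0.95 and 1.82 in the Smad3, Smad4 and Smad2 lines over 20, 17 and 18 members, beside 1.45 over 20 in wild-type cells. The same calculation with samples scaled to an equal robust SD gave 0.62, 0.37 and 1.42. These scaled values are not responses to TGF-β, because each ratio had its own factor. The matrix genes had medians of 1.08, 0.73 and 1.44 over 18, 21 and 17 members, beside 0.88 over 23 in wild-type cells, so the sets of members differ. The hepatocyte list had medians of −0.89, −0.75 and −1.05 over 18, 19 and 18 members, beside −1.003 over 20 in wild-type cells. Cholesterol synthesis genes had medians of 0.05 in the Smad3 line (percentile 57.1), −0.22 in the Smad4 line and −0.27 in the Smad2 line, against −0.58 in wild-type cells. The change of the response per gene, the knockdown ratio with TGF-β minus that without it, was also ranked against random lists. Its median for cholesterol synthesis genes was 0.62, 0.32 and 0.31 in the Smad3, Smad4 and Smad2 lines (percentiles 99.99, 99.91 and 99.94). For the immediate targets it was −0.18, −0.26 and 0.14 (0.93, 0.19 and 97.4). For the hepatocyte list it was −0.42 in the Smad2 line (percentile 0, with 4 of 18 lower) and −0.17 in the Smad3 line (2.15), and for the matrix genes 0.32 in the Smad2 line (99.99) and −0.19 in the Smad4 line (0.83). Further medians in the outer tails of the random lists were those of cell cycle (0.17), apoptosis (0.26) and ribosomal protein genes (−0.22) in the Smad2 line and of interferon-stimulated (−0.21), inflammatory (0.50, bootstrap SE 0.30) and unfolded protein genes (0.25) in the Smad3 line. These percentiles compare lists within samples, and no test across samples was possible with 1 sample per comparison. The wild-type levels with and without TGF-β enter the change of the response with the same sign in each line. If the lines were compared with the same wild-type RNAs, chance deviations of these RNAs would move a list alike in each line. The higher cholesterol synthesis medians in the Smad3, Smad4 and Smad2 lines thus cannot be counted as independent findings.

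**Figure D3:**
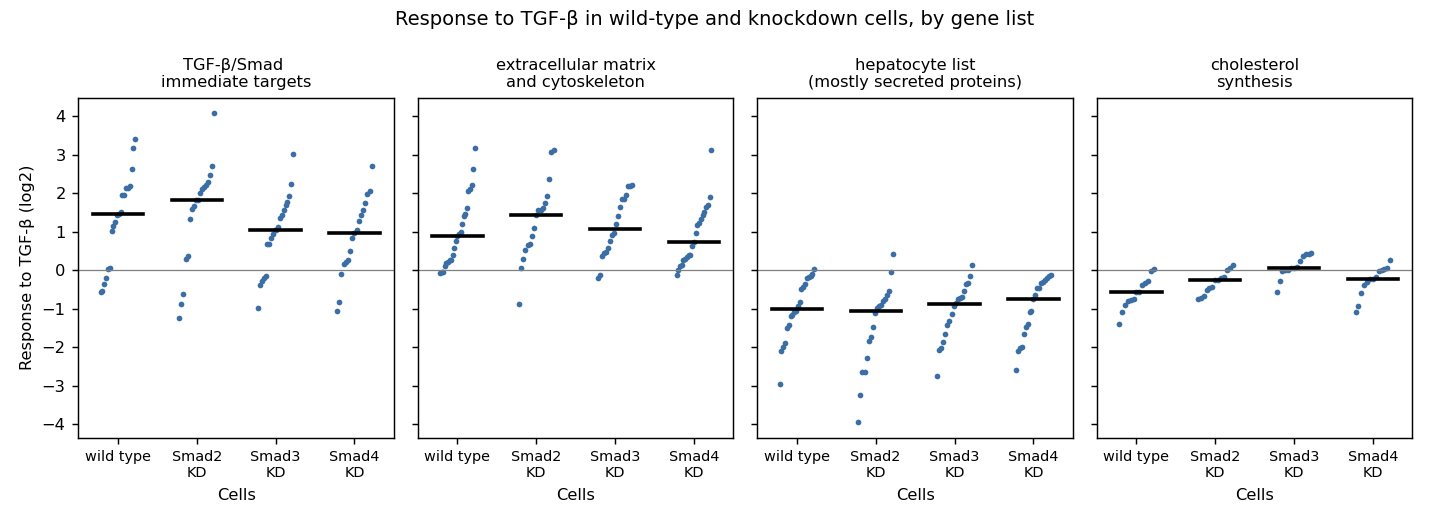
Response to TGF-β (log2) in wild-type cells and, computed from 3 samples, in the Smad2, Smad3 and Smad4 knockdown (KD) lines for 4 of the gene lists. Points are measured genes in order of size and black bars are medians. Except for cholesterol synthesis, the measured members of a list differ between the cells. The cholesterol synthesis median is −0.58 in wild-type cells and 0.05 in the Smad3 line.

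The knockdowns were also compared with each other. With TGF-β, 15 genes changed in the same direction in all 3 lines. Those with a value in every sample were GJA1, DKK3 and SCN9A, which were higher, and CDKN1A, HTRA1 and FST, which were lower; HTRA1 was at −1.53, −2.22 and −2.70 in the Smad2, Smad3 and Smad4 lines. GJA1, raised by TGF-β in wild-type cells, was higher still in the knockdowns (1.99, 2.01 and 1.47). Independent lists would share 0.019 genes and the simulations with a shared RNA gave a mean of 6.64 (2 to 13). Changes in the same direction were shared by 46 genes between the Smad3 and Smad4 lines (1.94 if independent; 25.7 simulated), 35 between Smad2 and Smad4 (1.30; 18.5) and 18 between Smad2 and Smad3 (2.51; 30.2). Without TGF-β the shared genes numbered 5 (0.021; 1.13), 2 (0.026; 1.32) and 8 (0.108; 3.56). The wild-type RNAs could not be split, so part of each excess may come from the shared controls.

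Within a line, the Smad2 knockdown shared 5 higher and 17 lower genes between the stimulated and unstimulated samples, against 0.070 and 0.276 expected of independent lists. The Smad3 knockdown shared 8 and 6 (0.670 and 0.182) and the Smad4 knockdown 2 and 3 (0.015 and 0.032). SPINK1, FGB and CDKN1A were lower in the Smad2 line in both conditions. Across genes, which are not independent replicates, the stimulated and unstimulated samples of a line correlated at r = 0.43, 0.33 and 0.26 for Smad2, Smad3 and Smad4. The wild-type response correlated with the stimulated knockdowns at r = 0.01, −0.59 and −0.44, with covariances of 0.002, −0.166 and −0.101 beside simulated ones of −0.118, −0.134 and −0.112. Spearman's rho was −0.02, −0.49 and −0.31. The stimulated knockdowns had covariances of 0.052 (Smad2 with Smad4), 0.034 (Smad3 with Smad4) and 0.00697 (Smad2 with Smad3), beside simulated ones of 0.067, 0.077 and 0.080.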

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

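Apart from the threshold of 3 robust SDs, which was fixed before the data were examined, the tests in this part were chosen after the results they concern had been seen. Each of the following genes passed 2-fold in opposite directions in 2 samples of 1 array each, and none of these differences was tested. C4BPA, which encodes a complement inhibitor, was lower in the stimulated Smad2 line and higher in the unstimulated one (−1.40 and 1.67, a difference of −3.07), and MAGEA1, outside the rule for named genes and chosen after its values were seen, did the same in the Smad3 line (−1.48 and 1.02, −2.51). With TGF-β the Smad2 and Smad3 lines differed in direction for 14 genes, among them ASPH (−1.59 and 2.83, −4.43), C4BPA (−1.40 and 1.45, −2.85), SERPINA3 (−1.29 and 1.04, −2.33) and IGFBP7 (1.14 and −1.05, 2.20). COL2A1 was higher in the stimulated Smad3 line and lower in the Smad4 line (1.56 and −1.36, 2.92). Without TGF-β the Smad2 and Smad3 lines differed in direction for 7 genes, among them GPX2 (−1.87 and 1.62, −3.50), DEFB1 (−2.08 and 1.12, −3.20) and SPANXN3 (1.08 and −1.59, 2.66).

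The Smad3 knockdown opposed the wild-type response at 2-fold in 5.77 times as many genes as the Smad2 knockdown. Chance variation of one stimulated wild-type RNA on all 4 arrays would enter the Smad2 and Smad3 samples alike, but their covariance was 0.00697 (bootstrap SE 0.0030) against −0.166 between the wild-type response and Smad3, which argues against it as the whole cause, and the larger spread of the Smad3 sample is argued against by a ratio that stayed at 4.50 with 3 robust SDs of each sample. A stimulated wild-type RNA used for the wild-type response and the Smad3 sample but not the Smad2 sample cannot be told apart from dependence on Smad3: both predict the sign of the correlation of −0.59, the RNA preparations are not known, and the no-effect simulations, though they fell short (r −0.45 and at most 100 opposed genes, against 173), assume equal noise in all RNAs and so set no bound. Deeper depletion in the Smad3 line stays open as well, since SMAD3 in its line was 1.21 higher on the log2 scale than SMAD2 in its own with TGF-β but differed by −0.24 without it, and protein levels were not analysed here. A larger part of Smad3 than of Smad2 in this response is a hypothesis drawn from these counts after they were seen, and these single samples leave it open.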

How the results depend on the processing

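Thresholds and filters moved the counts, and centring or the choice of probe moved none of the counts of changed or opposed genes by over 1.5 times. In the order wild-type response, Smad2, Smad3 and Smad4 with TGF-β, then without it, the changed genes numbered 1569, 669, 1200, 693, 221, 289 and 94 at 1.5-fold and 298, 56, 81, 45, 14, 12 and 4 at 3-fold. Opposed genes for Smad2, Smad3, Smad4 and all 3 numbered 108, 494, 292 and 30 at 1.5-fold and 7, 47, 23 and 1 at 3-fold, and after off-target genes were set aside 60, 394 and 223, and 3, 31 and 7. Genes changed the same way in all 3 lines were 53 with and 9 without TGF-β at 1.5-fold, and 1 and 0 at 3-fold. At 3 robust SDs the Smad2 and Smad4 samples with TGF-β had 276 and 232 changed genes, the Smad2, Smad3 and Smad4 samples without it 264, 219 and 216, and 13 were shared without TGF-β. Among genes with a value in all samples, 102, 225 and 68 changed with TGF-β and 30, 26 and 8 without, 15 and 41 were opposed for Smad2 and Smad4 and 4 for all 3, and 6 were shared with TGF-β; fewer genes enter there by construction. With thresholds scaled to the median probe-pair SD, added after the data had been seen, 355 genes changed in the wild-type response, 190 in the stimulated Smad3 sample and 153, 137 and 47 in the unstimulated Smad2, Smad3 and Smad4 samples; with its root mean square, added later still, 319 and 210, and 72, 216 and 96. In every one of these settings run for opposed genes, Smad3 had the most and Smad2 the fewest. With samples scaled to an equal robust SD, the immediate targets had a median of 1.02 in wild-type cells and the hepatocyte list −0.71. The calculation of responses from ratios so scaled gave 1.42, 0.62 and 0.37 for the targets in the Smad2, Smad3 and Smad4 lines. These are not responses to TGF-β, because each ratio had its own factor. As means over members, the targets were at 0.0238 and −0.35 in the stimulated Smad2 and Smad3 samples, and their response in the Smad2 line was 1.45. Among genes with a value in all samples, the fibroblast and stellate markers in the unstimulated Smad4 line turned from −0.13 to 0.12. Apart from the filter on genes, the cause of these shifts was not tested. Of the values of other lists, named genes and single directions under the alternatives fixed beforehand, 988 stayed within their error or within 1.5 times and 182 moved. Another 1 was counted as a turn of sign. For lists, a turn was counted only where the median lay in the outer tails of the random lists. Further lists turned without being counted, such as the fibroblast and stellate markers in wild-type cells (median −0.02, mean 0.27). With samples scaled to an equal robust SD, 88 values of named genes moved by more than the median probe-pair SD and 9 did not. No paired analysis was possible because each comparison had 1 sample. Signal over background was not analysed here, so its part in the precision of single ratios stays unknown.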

Other observations

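One test in this part, of the probe-pair SD over all 3 lines at once, was fixed before its result was seen; the other tests, and the genes named in the next paragraph, which lack a value in some samples and fall outside the rule for named genes, were chosen after their values were seen.

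The Nodal antagonists LEFTY2 and LEFTY1 rose by 7.72 and 6.81 in wild-type cells and the ligand BMP6 by 5.85. In the stimulated Smad3 line LEFTY2 was at −3.73 and LEFTY1 at −3.08, in the Smad4 line at −2.44 and −2.002, and in the Smad2 line at −0.29 and −0.41. BMP6 was at −0.71, −1.11 and 0.68 in the same lines. The inhibitory Smad gene SMAD6 rose by 2.20 and was at −1.48 in the Smad4 line, −0.94 in the Smad3 line and 0.23 in the Smad2 line. The methyltransferase gene AS3MT was at −5.67, the fructose kinase KHK at −5.28, the urea cycle gene ARG1 at −5.02 and the sulfotransferase SULT2A1 at −4.58, and none of these 4 had a value in the stimulated knockdowns. The secreted phosphoprotein SPP1 had values in 2 samples here, −6.09 in the stimulated Smad4 line and 2.51 in the unstimulated Smad3 line.

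More genes passed 2-fold with TGF-β than without it, by 3.28 times in the Smad2 line, 6.82 in the Smad3 line and 10.7 in the Smad4 line. With each threshold scaled to the sample's median probe-pair SD these ratios became 0.895, 1.39 and 2.17 (bootstrap SEs 0.230, 0.443 and 0.646), and with the root mean square of that SD 1.97, 0.972 and 1.125 (SEs 1.52, 0.162 and 0.251). The measures disagree on which line keeps an excess, since the SD of the Smad2 line widened 1.66 times with TGF-β by the median but 1.22 times by the root mean square. A wider technical spread of the stimulated samples thus cannot be told apart in any line from effects of the Smads that need TGF-β, which were not tested. Probes of a gene that respond unequally would widen the probe-pair SD too.

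The stimulated Smad2 and Smad4 lines shared 35 genes, more than the highest of the simulations (29), as did the Smad3 and Smad4 lines with 46 (35), but these simulations set no bound. Of the 35 genes 15 passed 2-fold the same way in the Smad3 line too, so they are not particular to Smad2 and Smad4. The signs were turned so that the knockdowns are positive. The wild-type median of the 31 shared genes with a value there was then −1.47 (bootstrap SE 0.33) against a knockdown median of 1.85. Of the 31 genes 25 had a wild-type value of the opposite sign and 6 of the same sign. Variation of a stimulated wild-type RNA common to these samples could be a source of the 25. It cannot be told apart from a dependence on the Smads, which predicts the opposite sign too. Neither by itself predicts the sign of the 6 genes. Standing differences of the Smad2 line could account for part of the set, with a median of 0.51 (SE 0.25) without TGF-β against 1.97 with it over the 22 genes with a value. Dependence on several Smads remains an untested hypothesis.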
